A study of Homo sapiens with 8 samples.

How the data were processed

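RNA was sequenced from U87 and T98, established human glioblastoma cell lines, 72 h after transfection with a control siRNA or an siRNA against LKB1, the kinase encoded by STK11. Each line and siRNA formed a group of 2 libraries, which gave 4 groups and 8 libraries. Per the labels' protocols, siRNA was delivered with Lipofectamine RNAiMAX and libraries were made with the TruSeq RNA kit, version V2, whose reads carry no strand. The number and sequences of the siRNAs are not given in the sources used here. The labels speak of duplicated cells and do not say whether the duplicates were separate transfections. They may be technical, in which case every p-value here measures only the spread between these samples.

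Reads were aligned with TopHat2 2.0.8b to hg19/GRCh37 and processed with edgeR, per the submitters' processing notes, which give no edgeR version. The read counter and the annotation version are not given in the sources used here. The deposited table holds 1 normalised signal value per gene and library, made by the authors, for 18815 RefSeq transcripts, of which 18787 gene symbols were kept. The values of this deposited signal equal edgeR pseudo-counts, in which reads are moved to a common library size with 1 common dispersion, here 0.06803, over the 4 groups. Inverting that function returned whole reads, within 0.05 read, for 100% of values in every library. The recovered totals ranged from 25223747 to 38019176 reads per library, and a symbol with several transcripts kept the one with the highest mean. Group names came from the labels, and coordinates (starts counted from 1) and RefSeq identifiers from the deposited table. GENCODE names on GRCh38 served only to match gene symbols and to obtain GC content, 3′ untranslated regions (3′ UTRs) and transcript sequences. No coordinates were converted between builds.

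A gene was tested where the value reached 10 in at least 2 libraries, which kept 14282 genes. Of these, 64 had values identical to another gene in every library, so their reads cannot be assigned to 1 gene. Genes that share sequence with close copies or pseudogenes, such as ribosomal proteins, the AKR1C family, keratins and actin-like ACTBL2, are uncertain for the same reason, as are genes overlapping on opposite strands. Tests used limma-trend (limma 3.58.1, R 4.3.3) on log2 of the value plus 1, with all 8 libraries, a mean for each group and 4 residual degrees of freedom. They were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Contrasts were LKB1 siRNA against control siRNA in T98 and in U87, the mean of both effects, their difference (T98 minus U87) and the control siRNA libraries of T98 against those of U87. The 43 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within each comparison. Member counts are given over all genes tested and adjusted over the list alone. No gene of the lists of mitochondrially encoded transcripts and of long non-coding RNAs was tested, because the deposited table holds protein-coding RefSeq transcripts.

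The filter, the test, its samples, the gene lists and the rule for named genes were fixed before the data were examined. The rule named STK11, its complex partners and the kinases it activates. For each knockdown effect in 1 line, it named the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold. Those genes also needed both LKB1 siRNA libraries on the same side of both control libraries, a higher group mean of at least 50 and a symbol that is not provisional. For the mean effect, a gene also had to pass in the same direction in both lines. For the difference and for the comparison of the lines, the rule took 5 and 5 genes without the condition on sides. In each list, it took up to 2 risen and 2 fallen members with the smallest adjusted p. Some genes and 1 list that met these rules are not reported here.

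The column names of the deposited table give a sequencing lane. Each group had 1 library on lane 2. The other was on lane 4 for T98 and on lane 5 for U87. The difference between the lanes, taken gene by gene within a group, correlated between the groups of 1 line at 0.72 (T98) and 0.81 (U87), and at 0.12 to 0.18 between groups of different lines. Libraries of 1 line therefore pair by lane, so a second fit was added with a lane term for each line and 2 residual degrees of freedom. It is called the lane-term fit, was chosen after the data were examined, and named its genes by the same rule. The replicate numbers follow the order of the samples and carry no pairing. In the lane-term fit, the comparison of the lines sets their lane 2 libraries against each other. Each line holds 1 residual degree of freedom in that fit. When a library is left out, the spread comes from the other line alone.

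The procedure was tested on simulated reads for the 14282 genes, of which 200 were changed alike in both lines. The simulated means kept the differences between the lanes of each line, and the spread was estimated with a lane term, so the simulation favours the lane-term fit by construction. At an absolute log2 change of 2, limma-trend without a lane term recovered 38% of changed genes in T98, 35% in U87 and 72% for the mean effect. At an absolute log2 change of 1, it recovered 0%, 0% and 10%, with 0 of 14082 unchanged genes called. The lane-term fit recovered 94%, 94% and 96% at a change of 2, and 54%, 59% and 71% at a change of 1. It called 16, 17 and 7 unchanged genes. The alternatives covered the pseudocount, the filter, the scaling, the threshold, limma without a trend, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, a block for lane 2 against the other lanes, and leaving out each library in turn. Every heptamer was scored by a z in each line over the 13244 tested genes with an annotated 3′ UTR, 92.7% of those tested. The z compares the log2 fold changes of genes with and without the heptamer. Those were first capped at the extremes and adjusted for 3′ UTR length, GC content and control expression.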

Results

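The 8 libraries separated first by cell line, then by sequencing lane, and the siRNA accounted for a smaller share of the variance. Over 14282 genes, the first principal component held 80.9% of the variance and parted T98 from U87. The second (7.22%) parted lane 2 from the other lanes, the third (4.85%) did so in opposite directions in the lines, and the fourth (4.15%) followed the siRNA. Libraries of the same group on different lanes differed by an SD of 0.86 to 0.89 on the log2 scale. LKB1 and control siRNA libraries of the same line and lane differed by 0.54 to 0.79. The test fixed beforehand has no lane term, so it counts the lane difference as noise. The lane-term fit, chosen after the data were examined, is given beside it. With 2 libraries per group, the p-values measure only the spread between these samples, which may be technical duplicates. Among the 6582 genes averaging 1000 or more reads, libraries of the same group differed by an SD of 0.48 to 0.57. The median counting error of those genes was 0.04. These values argue against duplicates that differ only by the sampling of reads. Whether they were separate library preparations of 1 RNA was not tested.

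STK11, which encodes LKB1, was lower under LKB1 siRNA in both lines. The STK11 transcript NM_000455 (chromosome 19, 1205798 to 1228434, hg19) had a mean of 2020 (SD 30) with control siRNA and 463.7 (SD 175) with LKB1 siRNA in T98, n = 2 per group. In U87 the STK11 means were 2243 (SD 286) and 372.7 (SD 17). LKB1 works in a complex with a STRAD pseudokinase and the scaffold MO25, and it activates AMPK and related kinases. With limma-trend, the STK11 log2 fold change was −2.58 (SE 0.28, adjusted p = 0.0466) in U87, −2.38 (SE 0.20, adjusted p = 0.00815) for the mean effect and −2.17 (SE 0.28, adjusted p = 0.0824) in T98, where it did not pass. In the lane-term fit, STK11 fell in both lines (T98 adjusted p = 0.00254, U87 adjusted p = 0.00195). Those calls were lost without any 1 U87 library, where the spread comes from the T98 libraries alone and the T98 effect itself is unchanged. Within lanes, the STK11 log2 fold change was −2.55 (lane 2) and −1.79 (lane 4) in T98, and −2.76 (lane 2) and −2.40 (lane 5) in U87. The STK11 call in U87 was lost without any 1 of the 8 libraries (adjusted p from 0.088 to 0.481 with limma-trend). The STK11 call for the mean effect was lost without T98 control 1 (adjusted p = 0.0624), U87 LKB1 1 (adjusted p = 0.0512) or U87 LKB1 2 (adjusted p = 0.052) with limma-trend.

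No other member of the LKB1 complex, AMPK or the related kinases passed limma-trend without a lane term. The salt-inducible kinase SIK1, which restrains CRTC coactivators, had a mean effect of 1.11 (SE 0.41, adjusted p = 0.246). SIK1 rose with a lane term (T98 adjusted p = 0.0079, U87 adjusted p = 0.00421), with log2 fold changes of 0.90 and 1.20 in the T98 lanes and 1.30 and 1.03 in the U87 lanes. The neuronal polarity kinase BRSK1 had a mean effect of 1.21 (SE 0.26, adjusted p = 0.0704), passed without T98 control 2 (adjusted p = 0.0429 with limma-trend), and rose in T98 in the lane-term fit (adjusted p = 0.00681). The mean effect with a lane term was negative for the AMPK catalytic subunit PRKAA1 at −0.50 (SE 0.12, adjusted p = 0.0206), for the AMPK subunit PRKAB2 at −0.46 (SE 0.11, adjusted p = 0.0192) and for the MO25 isoform CAB39L at −0.56 (SE 0.14, adjusted p = 0.0256). The pseudokinases STRADA (−0.28, SE 0.18, adjusted p = 0.51) and STRADB (−0.13, SE 0.19, adjusted p = 0.803) and the scaffold CAB39 (−0.14, SE 0.19, adjusted p = 0.794) did not pass for the mean effect with limma-trend. The AMPK subunit list had a median of −0.09 for the mean effect (camera adjusted p = 0.41) and the list of related kinases 0.09 (camera adjusted p = 0.427). The list of LKB1 complex genes was lower for the mean effect by camera (median −0.28, adjusted p = 0.0127, and adjusted p = 0.297 with an estimated correlation). STK11 was its 1 called gene of 5. The other members were negative too, and the list was not tested without STK11.

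**Figure D1:**
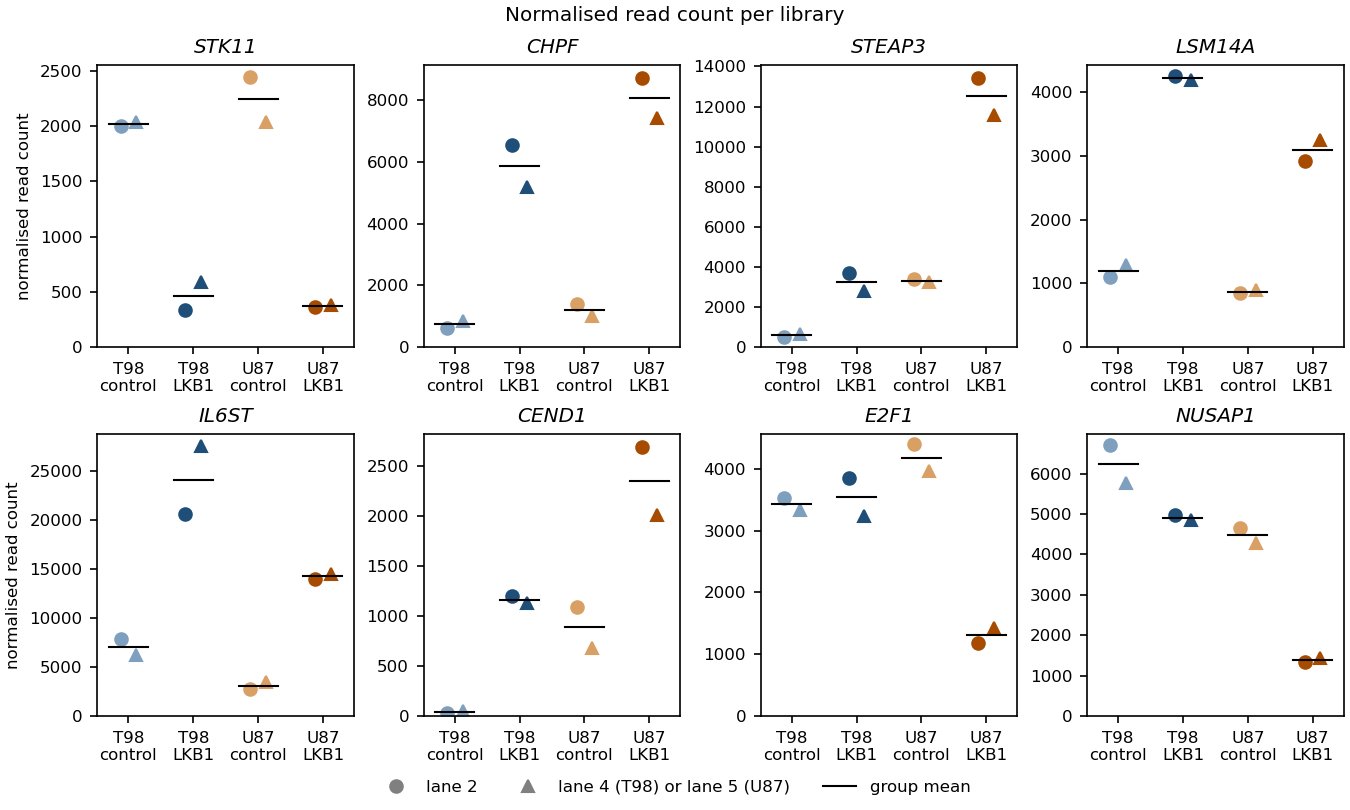
Normalised read count of 8 genes in each library, by line and siRNA, with lane 2 as circles, the other lane as triangles and group means as lines. The STK11 mean fell from 2243 to 372.7 in U87, and the CHPF mean rose from 1205 to 8079.

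In T98, 4 genes rose and 0 fell with limma-trend. CEND1, which drives neuronal precursors out of the cell cycle, rose from a mean of 35.71 (SD 12.7) to 1164 (SD 48.5), a log2 fold change of 5.03 (SE 0.35, adjusted p = 0.0121). CHPF, which extends chondroitin chains, rose from 738 (SD 153) to 5876 (SD 955), a log2 fold change of 3.0 (SE 0.25, adjusted p = 0.0202). STEAP3, which reduces iron taken up with transferrin, rose by 2.47 (SE 0.21, adjusted p = 0.0202), and LSM14A, a component of processing bodies, by 1.83 (SE 0.18, adjusted p = 0.0344). The 3′ UTRs of CHPF, STEAP3 and LSM14A carry the heptamer GCAGTAC, which is more frequent among risen genes in both lines and could be a target site of the control siRNA, whereas CEND1 carries none of the leading heptamers. Within lanes, CEND1 rose by 5.43 and 4.63, CHPF by 3.38 and 2.62, STEAP3 by 2.83 and 2.10, and LSM14A by 1.96 and 1.71 (lane 2, lane 4). At unadjusted p under 0.05 there were 1502 genes, edgeR called 3 higher and 0 lower, and DESeq2 called 191 higher and 159 lower. The CEND1 call was lost without T98 control 1 (adjusted p = 0.108), T98 LKB1 1 (adjusted p = 0.264) or T98 LKB1 2 (adjusted p = 0.0543), by limma-trend. LSM14A and STEAP3 were lost without any 1 library (adjusted p from 0.0543 to 0.378), and CHPF without 6 of the 8 (adjusted p from 0.0543 to 0.264), by limma-trend.

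The lane-term fit called 1211 genes higher and 1047 lower in T98. Among the largest rises in T98 with a lane term were the activin subunit INHBB at 3.76 (SE 0.56, adjusted p = 0.00933), the neuronal GTPase RAB39B at 3.73 (SE 0.33, adjusted p = 0.00249) and the epithelial keratin KRT4 at 3.63 (SE 0.41, adjusted p = 0.00497). The Fas inhibitor FAIM2 rose by 3.41 (SE 0.17, adjusted p = 0.000602), the bicarbonate transporter SLC4A8 by 3.34 (SE 0.20, adjusted p = 0.000937), the immune receptor ligand PIANP by 3.29 (SE 0.27, adjusted p = 0.00215) and the neuronal kinesin KIF5C by 3.18 (SE 0.19, adjusted p = 0.000937). Among the largest falls were the lipase LIPH at −3.75 (SE 0.35, adjusted p = 0.00254), the epidermal protein HRNR at −3.09 (SE 0.40, adjusted p = 0.00681), the Polycomb protein SCML2 at −2.78 (SE 0.47, adjusted p = 0.0134) and the adhesion protein vinculin, VCL, at −2.70 (SE 0.34, adjusted p = 0.00654). The protease inhibitor SERPINB2 fell by 2.70 (SE 0.16, adjusted p = 0.000937), the pentraxin PTX3 by 2.64 (SE 0.23, adjusted p = 0.00243), the ErbB4 ligand NRG4 by 2.63 (SE 0.34, adjusted p = 0.00681) and the ubiquitin-like UBD by 2.44 (SE 0.58, adjusted p = 0.0322). Several of these folds rest on few reads and are rough. In the T98 controls RAB39B had 2 and 7 reads, KRT4 10 and 5, and SLC4A8 17 and 9. With LKB1 siRNA in T98, LIPH had 4 and 10 reads and HRNR 5 and 16. SCML2 was −3.96 on lane 2 and −1.6 on lane 4 of T98, the latter being its value without T98 control 1 or T98 LKB1 1. LIPH, VCL and PTX3 carry the heptamer GAAGGAA, which is more frequent among fallen genes, and so do RAB39B and SLC4A8, which rose. SCML2 carries TGTATGA and GTATGAA, also more frequent among fallen genes, and so does RAB39B. The T98 count of the lane-term fit was 200 without T98 control 1, 208 without T98 LKB1 1, 3460 without T98 control 2, 3466 without T98 LKB1 2 and 0 without any 1 U87 library.

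In T98, ribosomal protein and glycolysis genes were higher as lists by camera, and NRF2 target and cytokine genes lower. Of the lists that were higher, ribosomal proteins (32 genes) had a median of 0.34, adjusted p = 8.97e-05, and adjusted p = 0.808 with an estimated correlation, and glycolysis (23 genes) of 0.41, adjusted p = 0.000481, and adjusted p = 0.325 with an estimated correlation. The amino acid and unfolded protein response list (24 genes) had a median of 0.47, adjusted p = 0.00475, and adjusted p = 0.808 with an estimated correlation, and growth-factor immediate-early genes (25 genes) of 0.34, adjusted p = 0.0155, and adjusted p = 0.626 with an estimated correlation. CREB targets (19 genes), which CRTC coactivators induce when LKB1-dependent kinases are inactive, had a median of 0.42, adjusted p = 0.041, and adjusted p = 0.801 with an estimated correlation. Hypoxia genes (24 genes) had a median of 0.30, adjusted p = 0.0448, and adjusted p = 0.808 with an estimated correlation. Of the lists that were lower, NRF2 targets (24 genes), which answer oxidative stress, had a median of −0.32, adjusted p = 0.00376, and adjusted p = 0.325 with an estimated correlation. NF-kB targets and cytokines (27 genes) had a median of −0.55, adjusted p = 0.0106, and adjusted p = 0.801 with an estimated correlation, and interferon-stimulated genes (36 genes) of −0.26, adjusted p = 0.0156, and adjusted p = 0.862 with an estimated correlation. The LKB1 complex had a median of −0.32, adjusted p = 0.0251, and adjusted p = 0.621 with an estimated correlation, and G2/M and mitosis genes (32 genes) of −0.23, adjusted p = 0.0339, and adjusted p = 0.854 with an estimated correlation. None of the 4 genes called over all genes in T98 belongs to a list. Adjusted over the list alone, 2 CREB targets were higher, 1 G2/M gene was higher and 1 lower, and 1 gene of the LKB1 complex was lower.

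Several of these T98 lists rested on single libraries. Without T98 control 1, camera gave adjusted p = 0.369 for CREB targets, 0.931 for G2/M genes (median 0), 0.704 for hypoxia, 0.0931 for the LKB1 complex and 0.227 for NF-kB. Without T98 LKB1 2, the adjusted p by camera was 0.268, 0.556, 0.876, 0.205 and 0.268 for the same lists. Without T98 control 2, it was 0.103 for the amino acid response, 0.0603 for immediate-early genes, 0.888 for interferon and 0.0624 for NRF2 targets. Without T98 LKB1 1, it was 0.191 for the amino acid response, 0.0735 for immediate-early genes, 0.987 for interferon and 0.615 for ribosomal proteins. YAP targets were lower in T98 only with a lane term (median −0.21, adjusted p = 0.0425, and adjusted p = 0.78 with an estimated correlation, by camera). Glycolysis passed whichever library was left out, and by fry (adjusted p = 0.0191). Glycolysis in the lane-term fit had 7 genes higher and 1 lower in T98, including the lactate transporter SLC16A1 at 0.65 (SE 0.11, adjusted p = 0.0135), PFKFB4 at 0.61 (SE 0.12, adjusted p = 0.018) and HK1 at −0.75 (SE 0.13, adjusted p = 0.0145). The stress cytokine GDF15 rose in T98 with a lane term by 1.82 (SE 0.19, adjusted p = 0.00405) and the phosphodiesterase PDE4B, a CREB target, by 1.87 (SE 0.18, adjusted p = 0.00274). The NRF2 targets AKR1B10 (−1.01, SE 0.13, adjusted p = 0.0066) and SRXN1 (−1.03, SE 0.16, adjusted p = 0.0111) fell in T98 with a lane term, as did the NF-kB inhibitor TNFAIP3 (−0.99, SE 0.16, adjusted p = 0.0109) and the G1 kinase CDK6 (−1.22, SE 0.18, adjusted p = 0.00925).

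In U87, 4 genes rose and 4 fell with limma-trend. CHPF rose by 2.76 (SE 0.25, adjusted p = 0.0466), and IL6ST, the shared receptor subunit gp130 of the interleukin-6 family, rose from a mean of 3094 (SD 485) to 14240 (SD 308), by 2.21 (SE 0.22, adjusted p = 0.0466). STEAP3 rose by 1.91 (SE 0.21, adjusted p = 0.0466) and LSM14A by 1.82 (SE 0.18, adjusted p = 0.0466). Besides STK11, the S phase transcription factor E2F2 fell by 1.93 (SE 0.21, adjusted p = 0.0466) and E2F1 by 1.69 (SE 0.19, adjusted p = 0.0466), and the spindle protein NUSAP1 fell by 1.69 (SE 0.17, adjusted p = 0.0466). E2F1 had a mean of 4184 (SD 311) with control siRNA and 1303 (SD 174) with LKB1 siRNA in U87, against 3429 (SD 143) and 3544 (SD 429) in T98. The 3′ UTRs of STEAP3 and IL6ST carry GAAGGAA beside GCAGTAC, that of E2F1 carries GAAGGAA, and those of E2F2 and NUSAP1 carry neither. Within lanes (lane 2, lane 5), CHPF rose by 2.64 and 2.87, IL6ST by 2.35 and 2.07, STEAP3 by 1.99 and 1.83, and LSM14A by 1.79 and 1.85. E2F2 fell by 2.14 and 1.72, E2F1 by 1.90 and 1.47, and NUSAP1 by 1.81 and 1.57. At unadjusted p under 0.05 there were 1268 genes, edgeR called 0, and DESeq2 called 207 higher and 284 lower. All 8 U87 calls were lost without any 1 of the 8 libraries (adjusted p from 0.088 to 0.481 with limma-trend).

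The lane-term fit called 755 genes higher and 844 lower in U87. The teneurin ODZ2, which guides neurites, rose by 2.76 (SE 0.33, adjusted p = 0.00365) in U87 with a lane term, the chemokine CXCL14 by 2.69 (SE 0.42, adjusted p = 0.00876) and the adhesion molecule ALCAM by 2.48 (SE 0.14, adjusted p = 0.00195). The kinase HIPK3 rose by 2.20 (SE 0.16, adjusted p = 0.00195) and the growth factor IGFL3 by 2.37 (SE 0.58, adjusted p = 0.0416), and actin-like ACTBL2, at 1 and 13 reads with control siRNA, by 3.34 (SE 0.55, adjusted p = 0.0105). LIPH fell by 3.78 (SE 0.35, adjusted p = 0.00195) in U87 with a lane term, as did SCML2 (−2.72, SE 0.47, adjusted p = 0.0125), the galactosyltransferase B3GALT4 (−2.78, SE 0.60, adjusted p = 0.0273) and the xylosyltransferase GXYLT1 (−2.21, SE 0.29, adjusted p = 0.00482). The zinc finger protein ZNF367 fell by 2.36 (SE 0.27, adjusted p = 0.00328), the hyaluronan receptor HMMR, which acts at the spindle, by 2.22 (SE 0.26, adjusted p = 0.00352) and the recombination factor RDM1 by 2.15 (SE 0.31, adjusted p = 0.00644). B3GALT4 was −4.17 on lane 2, where U87 LKB1 2 had 2 reads, and −1.39 on lane 5, which is its value without U87 control 1 or U87 LKB1 2. LIPH had 7 and 4 reads with LKB1 siRNA in U87, so its fold is rough. CXCL14, ALCAM and HIPK3 carry GCAGTAC, and LIPH, GXYLT1 and ZNF367 carry GAAGGAA, as does ACTBL2, which rose. The U87 count of the lane-term fit was 2402 without T98 control 1, 2403 without T98 control 2, 2407 without T98 LKB1 1, 2432 without T98 LKB1 2 and 0 without any 1 U87 library.

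Cell cycle genes fell as lists in U87. G2/M and mitosis genes (32 genes) had a median of −1.42, adjusted p = 1.5e-40, and adjusted p = 0.247 with an estimated correlation, with 1 gene lower over all genes and 31 adjusted over the list alone. G1/S and replication genes (32 genes) had a median of −1.03, adjusted p = 3.82e-33, and adjusted p = 0.247 with an estimated correlation, with 2 genes lower over all genes and 31 over the list alone. By fry, both lists passed (adjusted p = 0.021 and 0.0301). With a lane term, 30 G2/M and 31 G1/S genes were lower over all genes. Among them were the anaphase activator CDC20 (−1.50, SE 0.11, adjusted p = 0.00195) and the nucleotide reductase subunit RRM2 (−1.44, SE 0.12, adjusted p = 0.00195). All 64 members of both lists were negative in both U87 lanes (medians −1.30 on lane 2 and −1.13 on lane 5). The G1 regulators (16 genes) had a median of −0.34, adjusted p = 0.00672, and adjusted p = 0.247 with an estimated correlation. The G1 kinases CDK6 (−1.26, SE 0.18, adjusted p = 0.00616) and CDK2 (−0.75, SE 0.13, adjusted p = 0.0113) fell in U87 with a lane term. The LKB1 complex had a median of −0.24, adjusted p = 0.0208, and adjusted p = 0.266 with an estimated correlation, with 1 gene lower.

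**Figure D2:**
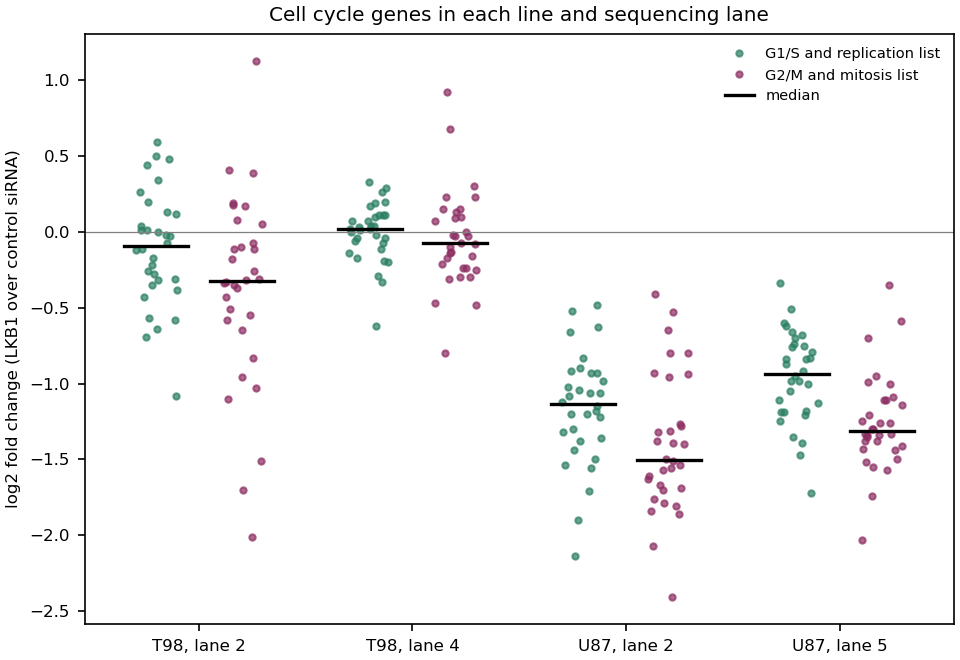
Log2 fold change (LKB1 over control siRNA) of 64 G1/S and G2/M genes in each line and lane, with medians as bars. Members were negative throughout in U87 (combined medians −1.30 and −1.13). In T98 the medians were near 0 (−0.20 and −0.02), and members went both ways, from −2.01 (HMMR) to 1.13 (PRC1) on lane 2.

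Adhesion, matrix and signalling lists were higher in U87 by camera. CREB targets had a median of 0.50, adjusted p = 0.000734, and adjusted p = 0.266 with an estimated correlation, and integrins and adhesion genes (26 genes) of 0.47, adjusted p = 0.00672, and adjusted p = 0.247 with an estimated correlation. Collagens and matrix proteins (28 genes) had a median of 0.42, adjusted p = 0.00672, and adjusted p = 0.32 with an estimated correlation, and immediate-early genes of 0.26, adjusted p = 0.00713, and adjusted p = 0.266 with an estimated correlation. Receptor tyrosine kinases and growth factors (31 genes) had a median of 0.20, adjusted p = 0.0156, and adjusted p = 0.266 with an estimated correlation, and the amino acid and unfolded protein response of 0.23, adjusted p = 0.0159, and adjusted p = 0.701 with an estimated correlation. Neuron markers (8 genes) had a median of 0.40, adjusted p = 0.0372, and adjusted p = 0.32 with an estimated correlation, and hypoxia genes of 0.18, adjusted p = 0.0453, and adjusted p = 0.612 with an estimated correlation. No member of these lists passed over all genes in U87, and adjusted over the list alone 1 adhesion gene was higher and 1 lower. The focal adhesion protein talin, TLN1, rose in U87 with a lane term by 1.85 (SE 0.16, adjusted p = 0.00195), and the laminin receptor ITGA6 by 1.31 (SE 0.16, adjusted p = 0.0038). Also with a lane term, fibronectin, FN1, rose by 1.08 (SE 0.15, adjusted p = 0.00546) and laminin LAMA4 by 0.92 (SE 0.11, adjusted p = 0.00396). The phosphatase DUSP4, an immediate-early gene, rose by 1.33 (SE 0.18, adjusted p = 0.00474), the signalling regulator RGS2, a CREB target, by 1.09 (SE 0.15, adjusted p = 0.00501), and the chaperone HSPA5 by 0.86 (SE 0.15, adjusted p = 0.0126). The ephrin receptor EPHB2 rose by 0.90 (SE 0.14, adjusted p = 0.00726), the crosslinking enzyme LOX by 1.07 (SE 0.15, adjusted p = 0.00658) and the synaptic SNAP25 by 1.78 (SE 0.20, adjusted p = 0.00318).

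Of the 12 U87 lists, CREB targets, G1/S, G2/M and integrins passed whichever library was left out. Without U87 control 1, camera gave adjusted p = 0.882 for the amino acid response, 0.281 for hypoxia, 0.0576 for immediate-early genes, 0.135 for the LKB1 complex and 0.088 for receptor tyrosine kinases. Without U87 LKB1 1, these 5 lists had adjusted p by camera of 0.78, 0.9, 0.0932, 0.0693 and 0.0693, with 0.0573 for G1 regulators and 0.0693 for neuron markers. Matrix and neuron lists were lost without U87 control 2 (adjusted p = 0.0559 and 0.173 by camera) and without U87 LKB1 2 (adjusted p = 0.137 and 0.0933 by camera). Passing only with a lane term were fatty acid synthesis (median 0.24, adjusted p = 0.0473, and adjusted p = 0.635 with an estimated correlation), TGF-beta response (0.27, adjusted p = 0.0272, and adjusted p = 0.446 with an estimated correlation) and matrix proteases (0.19, adjusted p = 0.0252, and adjusted p = 0.69 with an estimated correlation) by camera. Interferon-stimulated genes (−0.39, adjusted p = 0.0123, and adjusted p = 0.508 with an estimated correlation) and NRF2 targets (−0.22, adjusted p = 0.0493, and adjusted p = 0.446 with an estimated correlation) were lower by camera only with a lane term.

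For the mean effect of both lines, 143 genes were higher and 122 lower with limma-trend, of which 92 and 66 had an absolute log2 fold change of at least 1. The genes that passed for the mean and in each line were CHPF at 2.88 (SE 0.18, adjusted p = 0.00388), STEAP3 at 2.19 (SE 0.15, adjusted p = 0.00388) and LSM14A at 1.83 (SE 0.12, adjusted p = 0.00388), all 3 with GCAGTAC in the 3′ UTR. Among list members, the neurotrophin BDNF (1.38, SE 0.23, adjusted p = 0.0374) and PDE4B (1.38, SE 0.24, adjusted p = 0.0412), both CREB targets, rose, as did the ERK phosphatase DUSP5 (1.43, SE 0.27, adjusted p = 0.0493). Talin, TLN1, rose by 1.61 (SE 0.21, adjusted p = 0.021), while vinculin, VCL, its partner in focal adhesions, fell by 2.34 (SE 0.28, adjusted p = 0.0177). The lysosomal membrane protein LAMP2 (0.84, SE 0.14, adjusted p = 0.0378), the mTORC1 inhibitor AKT1S1 (0.77, SE 0.15, adjusted p = 0.0493) and the disulfide isomerase PDIA4 (0.69, SE 0.13, adjusted p = 0.0457) rose. The collagen COL5A1 (0.75, SE 0.13, adjusted p = 0.042), the YAP partner TEAD1 (0.71, SE 0.13, adjusted p = 0.0457) and the mesenchymal factor FOXC2 (1.39, SE 0.24, adjusted p = 0.0412) rose as well. HMMR fell by 1.81 (SE 0.20, adjusted p = 0.0158), NUSAP1 by 1.02 (SE 0.12, adjusted p = 0.0175), E2F2 by 0.92 (SE 0.15, adjusted p = 0.0347) and E2F1 by 0.82 (SE 0.13, adjusted p = 0.0337). The 3′ UTR of HMMR carries TGTATGA and GTATGAA. The TNF-induced TNFAIP2 (−1.20, SE 0.16, adjusted p = 0.021) and the small RNA nuclease DICER1 (−0.97, SE 0.17, adjusted p = 0.0392) fell. At unadjusted p under 0.05 there were 2263 genes, and edgeR called 187 and DESeq2 1033.

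The count for the mean effect moved with single libraries. It was 6 without T98 control 1, 57 without T98 control 2, 8 without T98 LKB1 1 and 172 without T98 LKB1 2. It was 8 without U87 control 1, 13 without U87 control 2, 4 without U87 LKB1 1 and 3 without U87 LKB1 2. Most genes named for the mean effect therefore depended on single libraries, and VCL passed in 3 of the 8 cases (adjusted p up to 0.094 with limma-trend). CHPF, STEAP3 and LSM14A passed for the mean effect whichever library was left out (adjusted p at most 0.0384 with limma-trend). The lane-term fit called 1886 genes higher and 1879 lower, and 0 without any 1 U87 library. CEND1 rose with a lane term by 3.23 (SE 0.15, adjusted p = 0.000206) and CXCL14 by 2.43 (SE 0.30, adjusted p = 0.00211). FAIM2 rose by 2.39 (SE 0.12, adjusted p = 0.000216), PIANP by 2.38 (SE 0.19, adjusted p = 0.000629) and ALCAM by 2.32 (SE 0.10, adjusted p = 0.000206). The neuronal kinase LMTK3 rose by 2.35 (SE 0.30, adjusted p = 0.00242) and the palmitoyltransferase ZDHHC22 by 2.33 (SE 0.40, adjusted p = 0.0062). ZDHHC22 had 0 reads in both U87 controls and 13 and 1 with LKB1 siRNA, so its fold is rough. In the T98 controls LMTK3 had 1 and 3 reads and CXCL14 0 and 6, so their folds are rough too. LIPH fell by 3.76 (SE 0.24, adjusted p = 0.000383) and PTX3 by 2.06 (SE 0.16, adjusted p = 0.000629), and SCML2 (−2.75, SE 0.34, adjusted p = 0.00203) was lower too. The tight junction protein CLDN12 fell by 1.99 (SE 0.14, adjusted p = 0.000535), GXYLT1 by 1.95 (SE 0.21, adjusted p = 0.00131) and the spindle protein CCDC99 by 1.89 (SE 0.19, adjusted p = 0.00112). Without a lane term, the CEND1 mean effect passed (adjusted p = 0.00608 with limma-trend) and was lost without U87 LKB1 2 (adjusted p = 0.0514).

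For the mean effect, cell cycle lists were lower, and CREB, glycolysis, stress and ribosomal lists higher, by camera. G2/M genes had a median of −0.79, adjusted p = 1.56e-19, and adjusted p = 0.297 with an estimated correlation, with 7 lower over all genes and 26 over the list alone. G1/S genes had a median of −0.50, adjusted p = 6.01e-15, and adjusted p = 0.299 with an estimated correlation, with 3 lower over all genes and 19 over the list alone. U87 carried most of both falls: in T98 the medians were −0.23 and −0.04, the latter not passing (adjusted p = 0.7 by camera), and 28 of the 64 members were negative in both lanes. NRF2 targets had a median of −0.24, adjusted p = 0.00631, and adjusted p = 0.297 with an estimated correlation, G1 regulators of −0.31, adjusted p = 0.00874, and adjusted p = 0.297 with an estimated correlation, and interferon-stimulated genes of −0.36, adjusted p = 0.0104, and adjusted p = 0.63 with an estimated correlation. CREB targets had a median of 0.42, adjusted p = 0.00239, and adjusted p = 0.299 with an estimated correlation, with 2 genes higher over all genes and 3 over the list alone. Glycolysis had a median of 0.27, adjusted p = 0.00239, and adjusted p = 0.297 with an estimated correlation, and the amino acid and unfolded protein response of 0.34, adjusted p = 0.00239, and adjusted p = 0.63 with an estimated correlation. Ribosomal proteins had a median of 0.22, adjusted p = 0.0018, and adjusted p = 0.63 with an estimated correlation, immediate-early genes of 0.19, adjusted p = 0.00335, and adjusted p = 0.297 with an estimated correlation and hypoxia genes of 0.20, adjusted p = 0.0127, and adjusted p = 0.63 with an estimated correlation. Collagens and matrix had a median of 0.33, adjusted p = 0.0159, and adjusted p = 0.368 with an estimated correlation, receptor tyrosine kinases of 0.33, adjusted p = 0.0279, and adjusted p = 0.299 with an estimated correlation and neuron markers of 0.50, adjusted p = 0.0279, and adjusted p = 0.368 with an estimated correlation.

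**Figure D3:**
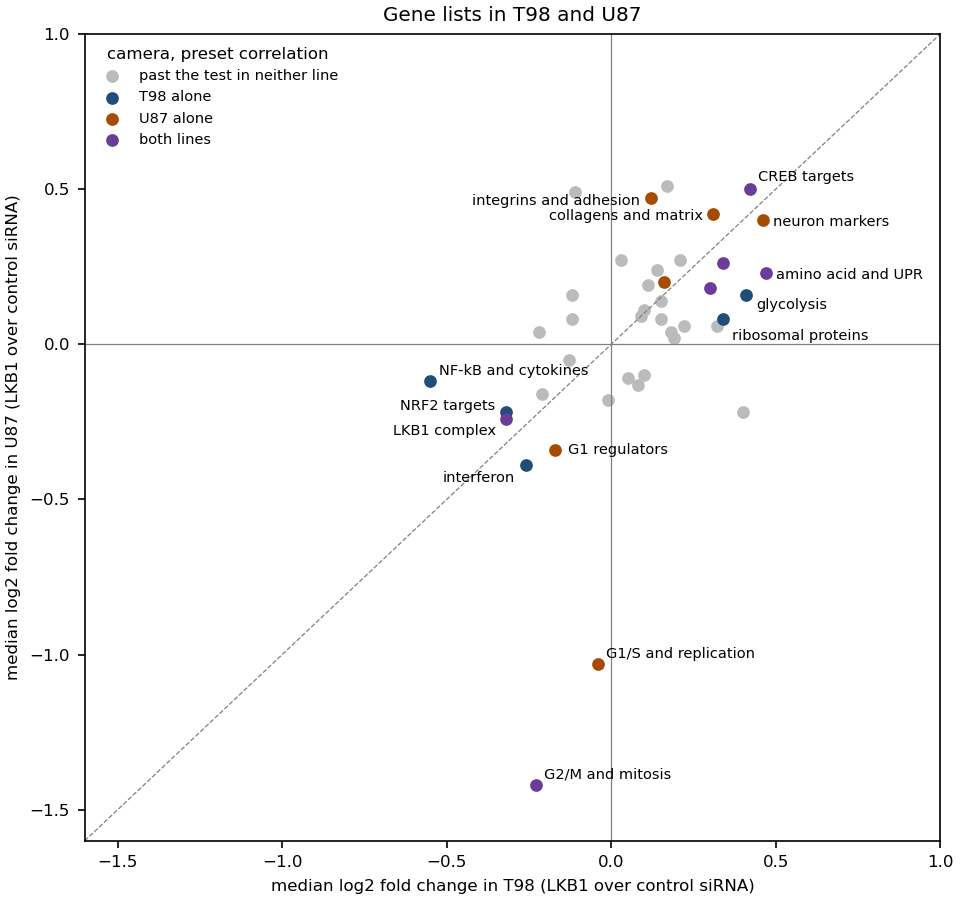
Median log2 fold change (LKB1 over control siRNA) of each gene list in T98 (horizontal) and U87 (vertical), coloured by the lines in which camera at the preset correlation passed. G2/M genes stood at −0.23 in T98 and −1.42 in U87, and ribosomal proteins at 0.34 in T98.

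Of the 15 lists that passed for the mean effect, 7 were lost without a library. By camera, the amino acid response was lost without U87 control 1 (adjusted p = 0.132) and U87 LKB1 1 (0.143). The interferon list was lost without T98 control 2 (adjusted p = 0.301 by camera) and T98 LKB1 1 (0.277). The matrix list was lost without T98 control 1 (adjusted p = 0.122 by camera), T98 LKB1 2 (0.113) and U87 LKB1 2 (0.0857). The hypoxia list was lost without T98 control 1 (adjusted p = 0.101 by camera), T98 LKB1 2 (0.199), U87 control 1 (0.0616) and U87 LKB1 1 (0.157). Neuron markers were lost without T98 control 1 (adjusted p = 0.101 by camera), T98 LKB1 2 (0.0537) and U87 control 2 (0.0709). Ribosomal proteins were lost without T98 LKB1 1 (adjusted p = 0.215 by camera) and U87 control 2 (0.0794). Receptor tyrosine kinases were lost without T98 control 2 (adjusted p = 0.141 by camera), T98 LKB1 1 (0.145), U87 control 1 (0.0756) and with a lane term (adjusted p = 0.0668). NF-kB targets were lower with a lane term by camera (median −0.33, adjusted p = 0.0156, and adjusted p = 0.494 with an estimated correlation). TGF-beta response (0.30, adjusted p = 0.0316, and adjusted p = 0.494 with an estimated correlation) and integrins (0.36, adjusted p = 0.00588, and adjusted p = 0.494 with an estimated correlation) were higher by camera with a lane term.

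The remaining lists did not pass for the mean effect by camera. In metabolism, cholesterol synthesis had a median of 0.12 (adjusted p = 0.815), fatty acid synthesis 0.15 (0.311), fatty acid oxidation 0.00 (0.945), nuclear-encoded respiratory chain subunits 0.12 (0.32) and regulators of mitochondrial biogenesis −0.02 (0.611). Autophagy and lysosome genes had 0.08 (0.319) and mTORC1 regulators 0.11 (0.189), the last passing by fry (adjusted p = 0.00518). Wnt targets had 0.11 (0.079), Notch genes −0.03 (0.7), YAP targets −0.14 (0.311), TGF-beta response 0.30 (0.0771) and matrix proteases 0.17 (0.189). Mesenchymal regulators had 0.02 (0.824), glioma stem and proneural markers 0.21 (0.965), core apoptosis genes −0.06 (0.651), replication histones 0.04 (0.945) and RNA interference genes 0.05 (0.824). Markers of other cell types had medians of −0.03 (0.517) for oligodendrocytes, 0.09 (0.945) for microglia and macrophages, 0.13 (0.427) for endothelial cells and 0.27 (0.311) for epithelial cells. NF-kB targets (−0.33, 0.0615) and integrins (0.36, 0.0543) did not pass without a lane term. The sterol pathway enzyme HMGCS1 fell with a lane term by 1.25 (SE 0.11, adjusted p = 0.000781), although the sterol carrier STARD4 rose by 0.85 (SE 0.11, adjusted p = 0.00237). HMOX1, which degrades haem, rose by 1.15 (SE 0.14, adjusted p = 0.00223) although AKR1B10 fell by 0.83 (SE 0.09, adjusted p = 0.00147).

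The knockdown effects differed between the lines in 5 lists by camera, whereas 0 genes differed with limma-trend (367 at unadjusted p under 0.05, edgeR 0, DESeq2 12). G1/S genes were less negative in T98 (median difference 0.95, adjusted p = 2.36e-35, and adjusted p = 0.345 with an estimated correlation), as were G2/M genes (1.14, adjusted p = 1.78e-39, and adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone, 13 G1/S and 26 G2/M genes differed. The effect on ribosomal proteins was higher in T98 than in U87 (0.30, adjusted p = 0.00615, and adjusted p = 0.89 with an estimated correlation), and NF-kB targets (−0.57, adjusted p = 0.0457, and adjusted p = 0.888 with an estimated correlation) and integrins (−0.37, adjusted p = 0.0187, and adjusted p = 0.345 with an estimated correlation) lower. NRF2 targets differed only with a lane term (median −0.22, adjusted p = 0.0297, and adjusted p = 0.842 with an estimated correlation, by camera). No list differed by fry. In the lane-term fit, 53 genes had a higher effect in T98 and 15 a higher effect in U87, and 0 genes differed without a trend. The former included E2F2 at 2.02 (SE 0.23, adjusted p = 0.0349), E2F1 at 1.73 (SE 0.20, adjusted p = 0.0349), CDC20 at 1.59 (SE 0.16, adjusted p = 0.0314) and the mitotic kinase PLK1 at 1.59 (SE 0.17, adjusted p = 0.0349). The latter included the receptor NOTCH3 at −1.92 (SE 0.23, adjusted p = 0.0349) and FN1 at −1.49 (SE 0.21, adjusted p = 0.0439). The difference for STK11 itself did not pass (0.41, SE 0.40, adjusted p = 1, and adjusted p = 0.522 with a lane term), which leaves unequal depletion open. Integrins were lost without T98 control 1 (adjusted p = 0.0651 by camera), U87 control 2 (0.0503) or U87 LKB1 2 (0.108). NF-kB was lost without T98 control 1 (adjusted p = 0.649 by camera), T98 LKB1 2 (0.549), U87 control 1 (0.513) or U87 LKB1 1 (0.714). Ribosomal proteins were lost without T98 control 2 (adjusted p = 0.246 by camera), T98 LKB1 1 (0.567), U87 control 1 (0.6) or U87 LKB1 1 (0.393). The lane-term count of 68 was 3 without T98 control 1, 229 without T98 control 2, 3 without T98 LKB1 1, 244 without T98 LKB1 2 and 0 without any 1 U87 library.

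Over all genes, the effects in T98 and U87 correlated at r = 0.46 (Spearman 0.47), and 68.4% of the 14282 genes had the same sign. Genes are not independent of one another, so no p is given for the correlation or for shared calls. CHPF, STEAP3 and LSM14A were higher in both lines, against 0.00112 expected if the calls were independent. Both lines take the variance of a gene from the same fit, so some excess over that number needs no shared effect. In the lane-term fit, 405 genes were higher in both lines (64 expected) and 309 lower in both (61.9 expected), such as ALCAM and LIPH, while 5 and 6 had opposite directions. Within a line, the effects on both lanes correlated at 0.58 in T98 and 0.59 in U87. Leaving out a library unbalances the lanes of its line. The correlation between the lines ranged from 0.32 to 0.40 when 1 library was left out.

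The lines themselves differed in many genes under control siRNA: 2607 were higher in T98 and 2779 in U87 with limma-trend. The scavenger receptor COLEC12 was higher in T98 by 10.65 (SE 0.86, adjusted p = 0.000148) and the chemokine CXCL12 by 10.24 (SE 0.65, adjusted p = 7.12e-05). The inflammatory cytokine IL36B (−11.57, SE 1.07, adjusted p = 0.000254), its family antagonist IL36RN (−10.86, SE 1.00, adjusted p = 0.000254), the granulocyte growth factor CSF3 (−11.52, SE 1.18, adjusted p = 0.000383) and the BMP antagonist GREM1 (−10.75, SE 0.49, adjusted p = 3.83e-05) were higher in U87. Reads were few on the low side, at 6 and 2 for COLEC12 and 1 and 7 for CXCL12 in U87, and at 5 and 0 for IL36B and CSF3 in T98, so these folds are rough. The transcriptional regulator KCTD15 was listed at 0 in both U87 control libraries and the microfibril protein MFAP2 at 0 in both T98 control libraries. MTAP, a methionine salvage enzyme, had 1785 and 1964 reads in T98 and 1 and 0 in U87. The adjacent cell cycle inhibitor CDKN2B had 1519 and 1180 reads in T98 and 1 and 0 in U87, and CDKN2A had 34 and 24 in T98 and was listed at 0 in U87. The count of 5386 was 3156 without T98 control 1 and 3297 without U87 control 1. The lane-term fit called 9037 genes, 3462 without U87 control 1.

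Of the lists, NRF2 targets stood out as higher in T98 than in U87 under control siRNA. They had a median of 2.41, adjusted p = 1.9e-08, and adjusted p = 0.0952 with an estimated correlation, with 19 of 24 genes higher over all genes and 20 over the list alone, led by the aldo-keto reductases AKR1B10 (5.0, SE 0.33, adjusted p = 8.37e-05) and AKR1C2 (4.48, SE 0.30, adjusted p = 8.38e-05). G2/M genes had a median of 0.73, adjusted p = 2.1e-05, and adjusted p = 0.57 with an estimated correlation, G1/S genes of 0.74, adjusted p = 0.00209, and adjusted p = 0.707 with an estimated correlation and interferon-stimulated genes of 0.87, adjusted p = 0.00875, and adjusted p = 0.707 with an estimated correlation. YAP targets had a median of 0.73, adjusted p = 0.0243, and adjusted p = 0.57 with an estimated correlation, and cholesterol synthesis of 0.83, adjusted p = 0.0243, and adjusted p = 0.761 with an estimated correlation. Lower in T98 were immediate-early genes (−1.09, adjusted p = 0.000114, and adjusted p = 0.21 with an estimated correlation) and NF-kB targets (−2.53, adjusted p = 0.000294, and adjusted p = 0.57 with an estimated correlation). Hypoxia genes (−1.35, adjusted p = 0.000381, and adjusted p = 0.57 with an estimated correlation), glycolysis (−0.69, adjusted p = 0.00318, and adjusted p = 0.21 with an estimated correlation), matrix proteases (−1.41, adjusted p = 0.0232, and adjusted p = 0.57 with an estimated correlation) and neuron markers (−2.52, adjusted p = 0.0232, and adjusted p = 0.57 with an estimated correlation) were also lower in T98. The angiogenic factor VEGFA (−4.05, SE 0.17, adjusted p = 3.83e-05), the ERK phosphatase DUSP6 (−4.13, SE 0.34, adjusted p = 0.000164) and the enolase ENO2 (−3.05, SE 0.25, adjusted p = 0.00017) were lower in T98. Over the list alone, 15 immediate-early, 20 NF-kB and 16 hypoxia genes were lower, against 14, 18 and 15 over all genes. Cholesterol synthesis was lost without T98 control 1 (adjusted p = 0.252 by camera) or U87 control 2 (0.132), interferon without T98 control 2 (0.127), and YAP targets without T98 control 1 (0.0946) or U87 control 1 (0.051). The interferon list was also lost with a lane term (adjusted p = 0.103 by camera), and ribosomal proteins passed only there (median 0.42, adjusted p = 0.0306, and adjusted p = 0.845 with an estimated correlation).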

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

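The tests of the cell cycle pattern were chosen after the result was seen. Cell cycle genes fell further in U87 than in T98: the difference of the effects (T98 minus U87) had a median of 0.95 for the G1/S list and 1.14 for the G2/M list. Both passed by camera at the preset correlation only (adjusted p = 0.345 with an estimated correlation for each list, and adjusted p = 0.124 by fry). A difference carried by 1 lane only is unlikely, because the T98 median minus the U87 median over both lists was 1.10 on lane 2 and 1.12 on the other lanes. Leading fallen heptamers within each gene would not account for the fall, since the 47 of 64 members without them still had a median of −1.19 in U87. That comparison does not address an effect passed on from a carrier such as E2F1, whose 3′ UTR holds GAAGGAA. Other seeds of the LKB1 siRNA, whose sequence is not given, stay possible. Weaker depletion of STK11 in T98 stays possible, although 1 pair of lanes goes against it. T98 lane 2 had a median of −0.20 where STK11 fell by 2.55. U87 lane 5 had a median of −1.13 where STK11 fell less, by 2.40. Each of these values rests on 1 library per siRNA, so they do not settle it. CDKN2A and CDKN2B were near 0 reads in U87, so the lines could also differ in cell cycle control, which no test here addressed.

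The integrins and adhesion list differed with a median of −0.37, by camera at the preset correlation only (adjusted p = 0.0187, and adjusted p = 0.345 with an estimated correlation). NF-kB targets and cytokines differed with a median of −0.57 (camera adjusted p = 0.0457, and adjusted p = 0.888 with an estimated correlation), and were lost without T98 control 1 (adjusted p = 0.649), T98 LKB1 2 (adjusted p = 0.549), U87 control 1 (adjusted p = 0.513) or U87 LKB1 1 (adjusted p = 0.714). Ribosomal proteins differed with a median of 0.30 (camera adjusted p = 0.00615, and adjusted p = 0.89 with an estimated correlation). Their transcripts share sequence with many pseudogenes.

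The single genes named here differed in the lane-term fit by limma-trend, which was chosen after the data were examined, and had adjusted p = 1 with limma-trend without a lane term. Without a trend, 0 genes differed in the lane-term fit, so none of these calls held there. Without a lane term, 23 genes differed with no filter and 12 by DESeq2. The neuronal differentiation gene CEND1 rose further in T98, by 3.60 (SE 0.30, adjusted p = 0.0271), from a T98 control level far below that of U87. The bicarbonate transporter SLC4A8 differed by 2.87 (SE 0.28, adjusted p = 0.0271), the ubiquitin ligase NEURL1B by 2.41 (SE 0.24, adjusted p = 0.0271), the kinesin KIF5C, which carries GCAGTAC, by 2.17 (SE 0.27, adjusted p = 0.0415) and the Fas inhibitor FAIM2 by 2.04 (SE 0.24, adjusted p = 0.0349). In the other direction, the convertase PCSK5 differed by −2.49 (SE 0.32, adjusted p = 0.0439) and the protease inhibitor SERPINB2 by −2.45 (SE 0.22, adjusted p = 0.0271). Complement C3 differed by −2.43 (SE 0.22, adjusted p = 0.0271), the retinal dehydrogenase ALDH1A1 by −2.12 (SE 0.30, adjusted p = 0.0439) and the zinc finger protein BNC2 by −2.07 (SE 0.31, adjusted p = 0.0467). In U87, ALDH1A1 had only 9 and 5 reads with control siRNA and 11 and 13 with LKB1 siRNA. SLC4A8 had 17 and 9 reads in the T98 controls. PCSK5 and BNC2 carry both GCAGTAC and GAAGGAA.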

How the results depend on the processing

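Counts are genes past adjusted p under 0.05 with limma-trend unless another tool is named, and values are those of the fit without a lane term unless a lane term is named. Every setting with a lane term, and the settings with genes lacking the leading heptamers, were chosen after the data were examined. Genes without the leading heptamers are 6568 of the 14282, so a smaller count among them need not come from the heptamers. When a library is left out, its group keeps 1 library that is assumed to vary like the others, and the lanes of that line are no longer balanced. A lane term then leaves 1 residual degree of freedom, which belongs to the other line. Calls without a T98 library thus rest on the U87 spread, and calls without a U87 library on the T98 spread. No paired analysis was possible by replicate number, because the numbers follow only the order of the samples. Libraries were paired by lane instead, in the lane-term fit. Of the named results that a setting covered, 0 reversed. A change of sign counted as reversed only where the result passed in the main fit or in the setting. Where it passed in neither, the result was counted as the same, so such signs may have changed. Settings covered all 96, except that the higher filter limit covered 92, only the libraries of the comparison 48, and genes without the leading heptamers 32.

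In T98, LKB1 against control siRNA gave 4 genes. It gave 13 with no filter, 0 with only the libraries of the comparison, 0 with limma without a trend, 350 with DESeq2, 0 at adjusted p under 0.01, and 1 among genes without the leading heptamers. Leaving out each library in turn gave 0 to 2. It gave 2258 with a lane term, and 161 without a trend, 2626 with edgeR, 2540 with DESeq2 and 892 among genes without the leading heptamers. Without T98 control 1 and with a lane term it gave 200, without T98 control 2 3460, without T98 LKB1 1 208, without T98 LKB1 2 3466, and 0 without each U87 library (U87 control 1, 0, U87 control 2, 0, U87 LKB1 1, 0, U87 LKB1 2, 0).

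In U87, LKB1 against control siRNA gave 8 genes. It gave 30 with no filter, 14 with a filter limit 5 times higher, 0 with TMM factors, 32 with quantile normalization, 0 with median-of-ratios factors, 0 with only the libraries of the comparison, 0 with limma without a trend, 0 with edgeR, 491 with DESeq2 and 82 with a block for lane 2 against the other lanes (index sets). It gave 0 at adjusted p under 0.01, 0 among genes without the leading heptamers, and 0 without any 1 library. It gave 1599 with a lane term, and 263 without a trend, 1999 with edgeR, 1914 with DESeq2 and 544 among genes without the leading heptamers. These U87 counts with a lane term were 2402 without T98 control 1, 2403 without T98 control 2, 2407 without T98 LKB1 1, 2432 without T98 LKB1 2, and 0 without each U87 library.

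The mean effect over both lines gave 265 genes. It gave 148 with no filter, 4 with limma without a trend, 1033 with DESeq2, 559 with the index-set block, 158 with an absolute log2 fold change of at least 1, 8 at adjusted p under 0.01 and 8 among genes without the leading heptamers. Leaving out each library in turn gave 3 (without U87 LKB1 2) to 172 (without T98 LKB1 2). Adding a lane term gave 3765, and 2162 without a trend, 3853 with edgeR, 3577 with DESeq2 and 1505 among genes without the leading heptamers. These mean counts with a lane term were 2498 without T98 control 1, 4750 without T98 control 2, 2515 without T98 LKB1 1, 4747 without T98 LKB1 2, and 0 without each U87 library.

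The difference between the lines gave 0 genes. It gave 23 with no filter and 12 with DESeq2. It gave 68 with a lane term, and 0 without a trend, 148 with edgeR, 415 with DESeq2 and 112 among genes without the leading heptamers. The lane-term count of the difference was 3 without T98 control 1, 229 without T98 control 2, 3 without T98 LKB1 1, 244 without T98 LKB1 2, and 0 without each U87 library.

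T98 against U87 under control siRNA gave 5386 genes. It gave 2838 at adjusted p under 0.01 and 2395 among genes without the leading heptamers, and leaving out each library in turn gave 3156 to 5369. It gave 9037 with a lane term, and 8155 without a trend, 9002 with edgeR and 8150 with DESeq2. The lane-term count of the lines was 9540 without T98 control 2, 9546 without T98 LKB1 1, 9549 without T98 LKB1 2 and 3462 without U87 control 1.

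In T98 the STK11 effect was −2.17. It was −2.12 with DESeq2 (adjusted p = 2.36e-08). It stayed with a lane term at −2.17 and passed with limma-trend (adjusted p = 0.00254), without a trend (adjusted p = 0.0484), with edgeR (adjusted p = 0.000989), with DESeq2 (adjusted p = 4.12e-20) and among genes without the leading heptamers (adjusted p = 0.00192). With a lane term and 1 T98 library left out it was −2.55 or −1.79, each from 1 LKB1 siRNA library against 1 control library. Leaving out each library in turn gave −2.57 to −1.78 without a lane term.

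In U87 the STK11 effect was −2.58 and passed. It did not pass with no filter (adjusted p = 0.0729 by limma-trend), with TMM factors at −2.57 (adjusted p = 0.0527), with median-of-ratios factors at −2.55 (adjusted p = 0.0549), with only the libraries of the comparison (adjusted p = 0.244), with limma without a trend (adjusted p = 0.186), with edgeR (adjusted p = 0.0694) or among genes without the leading heptamers (adjusted p = 0.0522). Leaving out each library in turn gave −2.71 to −2.45. Without a U87 library and with a lane term it was −2.76 or −2.40 (adjusted p from 0.216 to 0.383 with limma-trend). The mean STK11 effect of −2.38 did not pass with limma without a trend (adjusted p = 0.0503), and leaving out each library in turn gave −2.57 to −2.18. Without a U87 library and with a lane term it was −2.47 or −2.29 (adjusted p from 0.085 to 0.112 with limma-trend).

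The correlation of the effects between the lines was 0.46 over all genes. It was 0.35 with no filter, 0.83 among genes past the threshold in either line, 0.61 among such genes with a lane term, and 0.32 to 0.40 with each library left out in turn.

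Camera at the preset correlation gave 11 lists in T98, 12 in U87, 15 for the mean effect, 5 for the difference and 13 for the lines under control siRNA. Camera with an estimated correlation gave 0 in each comparison, without and with a lane term. Fry gave 2, 5, 6, 0 and 27 lists in the same order. Camera at the preset correlation with a lane term gave 18 in U87. Among genes without the leading heptamers it gave 3 in U87, 8 for the mean effect and 7 for the lines, and 4 in U87 and 7 for the mean effect with a lane term. Leaving out each library in turn gave 7 to 12 lists in T98 and 4 to 9 for the difference. The median of G2/M genes in T98 was −0.44 to 0 over the libraries left out. Without T98 control 1 the fall of the G2/M list in T98 was lost (median 0, adjusted p = 0.931 by camera).

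Of the 96 named results, edgeR left 88 the same and 8 weaker. DESeq2 left 72 the same, 1 weaker and 23 stronger. Limma without a trend left 78 the same and 18 weaker, and the lane term left 47 the same and 49 stronger. Many of the 96 were named because they passed in the lane-term fit. Those among them that failed without a lane term were bound to be stronger with it. The 49 are therefore no evidence for the lane term.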

Other observations

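Many genes called higher for the mean effect shared a short sequence in their 3′ UTRs, and so did many called lower. Of 15992 heptamers scored over 13244 genes, GCAGTAC had the highest z in T98 (11.05) and in U87 (15.4). GAAGGAA had the lowest in both (−6.90 and −7.51). For the difference between lanes, which involves no change of siRNA, z ranged from −4.98 to 4.45. Carriers of GCAGTAC (700 genes) had a median log2 fold change of 0.12 in T98 and 0.28 in U87, against 0.01 and −0.01 for other genes. The difference of these medians was 0.06 (lane 2) and 0.19 (lane 4) in T98, and 0.35 (lane 2) and 0.24 (lane 5) in U87. Carriers of GAAGGAA (2860 genes) had medians of −0.10 in T98 and −0.03 in U87, against 0.05 and 0.01, so their unadjusted shift in U87 was small. Unlike z, these medians are not adjusted for 3′ UTR length, GC content or expression. By lane, GAAGGAA carriers differed from other genes by −0.23 (lane 2) and −0.05 (lane 4) in T98, and by −0.01 (lane 2) and −0.07 (lane 5) in U87. Among genes called for the mean effect, GCAGTAC was in 60 of 138 called higher (43.5%) and in 5.3% of those called lower, and GAAGGAA in 60 of 113 called lower (53.1%) and in 23.2% of those called higher. With a lane term the shares were smaller, at 224 of 1776 (12.6%) against 3.3% for GCAGTAC and 576 of 1741 (33.1%) against 19.7% for GAAGGAA. The 236 genes with GCAGTACA, a match of 1 more base, had medians of 0.21 in T98 and 0.37 in U87.

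The 3 tests of the sequence pattern, the heptamers of the third taken from the data, and those of length, GC content and depth were written before their results were seen. The test of a common lane effect and both tests by splits were chosen after. Heptamers found in T98 could be sites of siRNA seeds, the bases by which a small RNA pairs with 3′ UTRs. A seed of the control siRNA would repress its carriers in control libraries, so they would seem to rise under LKB1 siRNA: GCAGTAC, highest in T98, ranked 1 in U87. A seed of the LKB1 siRNA would repress carriers under LKB1 siRNA: GAAGGAA, lowest in T98, ranked 1 from the bottom in U87. Both results are what seed effects would give in these tests. Any other effect on 3′ UTRs that both lines share would give them too, so the tests cannot single out siRNA seeds. If seeds are the cause, the rise of CHPF, STEAP3, LSM14A and IL6ST may owe nothing to LKB1. The fall of LIPH, VCL and PTX3 may not either. The same goes for HMMR, SCML2 and CLDN12, which carry TGTATGA and GTATGAA, also among the lowest heptamers in both lines. RAB39B and IL6ST carry both too, but rose. Whether the fallen heptamers GAAGGAA and TGTATGA belong to siRNAs aimed at STK11 stays open. The longest STK11 transcript, named for the test, holds 1 of the 2 (TGTATGA). STK11-201 and STK11-205, looked at afterwards, each hold both in their coding part. They were the STK11 transcripts with a coding part in the GENCODE basic annotation, and the longest transcript was not among them. STK11-201 also holds both with 1 more base (GAAGGAAA and TGTATGAA). The longest transcript holds both heptamers in 13.9% of tested genes and both longer forms in 3.3%, and the siRNA sequences are not given in the sources used here.

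Libraries of the same group differed between lanes more than siRNAs did within a lane. Length and GC content are unlikely causes, because they explained at most 3.87% of the variance of the lane difference. Sequencing depth is unlikely too, because the difference correlated at 0.72 or more between the groups of a line, which counting noise would not give. The SD bound of 0.5 written beforehand for depth was missed by 1 group (0.48 in U87 LKB1), so this rests on the correlation, which was taken up afterwards. A lane effect common to both lines could not account for most of the difference, since the highest correlation between groups of different lines was 0.18. Some of it was shared, because principal component 2 (7.22% of the variance) parted lane 2 from the other lanes in both lines. Outside lane 2 the lines ran on different lanes, so the correlation cannot address effects particular to those lanes, which stay possible. A separate transfection or culture for each lane set could also account for the difference, but was not tested.

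The count of genes with a mean effect was compared with splits of the libraries into other groups that keep 2 libraries of each line on both sides. These fits held 1 effect common to both lines instead of an effect for each line. The counts of the real split therefore differ from the 265 (no lane term) and 3765 (lane term) given above. With the line as covariate, 1 of 18 such splits, the real one, gave as many genes (343), and the highest other, 189, was the split by lane set. With a lane term, 1 of 8 splits that part every lane pair gave as many (2335, highest other 0). Both sets of splits are too few for a share under 0.05.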
